A study of Rattus norvegicus with 39 samples.

How the data were processed

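RNA was sequenced from punches of the ventral tegmental area of adult rats, with 1 library per sample, 39 libraries in all. Per the labels' protocols, brains were sectioned on a block after decapitation, the punches were frozen on dry ice, and libraries were made from total RNA with a directional kit (NEBNext Ultra II). The labels call the samples of a group biological replicates and do not say whether each came from a separate rat, so p-values measure the spread between these samples. Each library was put in 1 of 6 groups by the sex and the experimental group in its title.

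The deposited table holds 1 value per gene and library for 37403 genes, of which 3999 were 0 in every library. Per the submitters' processing notes, Trim Galore, kallisto and DESeq2 were used, with no versions, roles or order. The genome build and the annotation behind the values are not given in the sources used here, so no coordinates are printed. The table is named normalized, but the values the authors deposited are estimated counts that keep each library's depth. The 39 library totals ran from 15.2 M to 63.1 M (median 24.5 M), all 39 were whole numbers within 0.00022, and median-ratio size factors ran from 0.605 to 2.48 and followed the totals (r = 0.971 over the 39 libraries). In 72 olfactory receptor genes with low values, the smallest step of a gene had a median of 2.58 and hardly depended on the size factor (slope 0.045), so a single read counted for more than 1, as in counts scaled for transcript length. Only 0.205% of the values between 0.5 and 20 were whole within 0.001, so whole reads could not be recovered. Length scaling multiplies all counts of a gene alike, which leaves its fold changes in place but overstates how precisely the low values of short genes were counted. All 37403 gene symbols had an entry in the RefSeq gene table of assembly GRCr8, which was used for names and gene types only. Symbols are given as in the deposited table, and those of provisional genes were not used as names.

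The values were rounded to whole numbers and analysed as counts with edgeR 4.0.16 in R 4.3.3. A log-scale test with limma had been written down beforehand because the table is named normalized; since the values turned out to be estimated counts, edgeR's quasi-likelihood test became the main test and limma on log2(value + 1) an alternative. Genes with a value of at least 10 in at least 4 libraries, the size of the smallest group, were kept. This left 22493 genes, 16960 of them protein-coding, 4443 long non-coding and 1000 small RNA genes, with 5891 provisional symbols among the genes tested. Libraries were scaled with TMM, 1 model with a mean for each of the 6 groups was fitted over all 39 libraries, and 11 comparisons were tested two-sided (estimateDisp, glmQLFit, glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method over the 22493 genes within a comparison, and an adjusted p under 0.05 counts as a pass. Fold changes are on the log2 scale with a standard error (SE) derived from the F statistic, and levels are CPM, counts scaled with TMM to a common library size, as mean ± SD over libraries. Adjusted p-values of single genes come from edgeR unless another tool is named.

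Groups of genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Of 34 lists fixed in advance, 32 had at least 5 measured members and were tested. The camera test was repeated with a correlation estimated from the data, and fry was run as a test of whether the members moved one way on balance. Members are also counted by an adjusted p over all genes and adjusted over the list alone. A list score is the mean log2 CPM of the members in a library (prior count 2), compared between groups with an exact permutation test adjusted over the lists. Gene types that share sequence, such as Hspa1a with Hspa1b, the RT1 genes, and pseudogenes with their parents, may exchange reads in the authors' counting, and whether strand was used in counting is not given in the sources used here, so values of such genes and of antisense partners are uncertain.

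Genes named in the text were chosen by a rule written in advance. For each comparison with saline these are the genes that passed, up to 10 in each direction by adjusted p, filled to 5 in each direction by the smallest p with genes that did not pass, up to 10 further list members that passed, and 10 fixed genes (Th, Slc6a3, Oprm1, Oprk1, Penk, Pdyn, Bdnf, Fos, Fkbp5 and Gfap). For the other comparisons they are up to 5 in each direction, filled to 3, and, between the sexes, the Y-linked and X-linked list members. Other genes in the text were named after their values were seen. The design, the lists, this rule and the first set of alternatives were fixed before the data were examined.

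The scripts were tested on simulated counts with the means and library sizes of the 22493 genes and a known set of changed genes. In a simulated D1 against saline comparison of males, 38.8% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 78.8% of those changed 4-fold were called, and 8.15% of the calls were unchanged genes. The shares were 25.4%, 53.7% and 66.7% for D1 against saline in females, with 6.73% unchanged genes among the calls. They were 38.8%, 62.7% and 80.3% for females against males in saline, with 10.4% unchanged genes among the calls. The simulated counts were drawn for each gene on its own, with no correlation between genes and no regional differences or outlying libraries. The real libraries had such differences, so these shares test the scripts and may not hold for the real comparisons.

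Alternatives changed 1 choice at a time: DESeq2 1.42.0 (Wald test), limma on log2(value + 1) or log2(value + 5), limma on log2 CPM, median-ratio size factors, quantile normalization, no filter on low values, a block for the replicate number, a block for the library series (the first digit of a library name, or the name Blue), no Blue libraries, array quality weights, a separate fit per sex or condition, and leaving out each library in turn. Counts by edgeR or DESeq2 on recovered reads had been planned and were run on the rounded estimated counts instead. Chosen after seeing the data were a fit of protein-coding genes alone, an adjustment over protein-coding genes alone, robust edgeR, limma voom with quality weights, 3 principal components of regional marker genes as covariates, and leaving out the libraries low in Slc6a3. No column of the table was left unused. Limma on log2(value + 1) and on log2(value + 5) used the deposited values without scaling for depth, so both fits also carry differences in depth. Limma on log2 CPM was scaled with TMM.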

Results

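The ventral tegmental area (VTA) is a midbrain region that holds dopamine neurons and neighbouring GABA and glutamate neurons. Bulk RNA-seq profiled VTA punches of male and female rats that had self-administered saline or morphine intravenously. Morphine groups were sampled at 1 day (D1) or 30 days (D30) of abstinence, and saline groups 1 day after their last session. There were 8 male saline, 9 male D1, 7 male D30, 6 female saline, 4 female D1 and 5 female D30 libraries. Library totals ran from 15.2 M to 63.1 M estimated counts, with group means between 23.4 M (female D30) and 29.8 M (male D1). The study asked how expression differed between the sexes and between abstinence times. No saline group was sampled at 30 days, so time since the last session and age went with the D30 groups. Xist, the non-coding RNA of the inactive X chromosome, was between 70.0 and 114 CPM in females and at most 0.393 CPM in males. The Y-linked helicase gene Ddx3y was between 34.5 and 53.6 CPM in males and at most 0.759 CPM in females, so 39 of 39 libraries matched their sex label.

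Genes that mark the VTA and its neighbours varied widely between libraries of a group. Slc6a3, the dopamine transporter, had a median of 847 CPM over the 39 libraries and a range of 13.9 to 1685 CPM. It lay under 0.25 of the median in 7 libraries, against 290 CPM or more in the other 32. The 7 were male saline replicates 7 and 8, male D1 replicate 8, male D30 replicates 6 and 7, female saline replicate 5 and female D30 replicate 2. Th, the rate-limiting enzyme of dopamine synthesis, was at most 561 CPM in these 7 libraries. Male D1 replicate 9, with 290 CPM of Slc6a3 and 559 CPM of Th, was close to them. It was not counted among the 7 and stayed in the fits without them. Tph2, which marks serotonin neurons of the raphe, averaged 26 ± 33 CPM in male saline (SD, n = 8), 72.1 ± 53.5 in male D1 (n = 9), 69.2 ± 49.2 in male D30 (n = 7). In females it averaged 3.18 ± 2.45 in female saline (n = 6), 86.0 ± 63.6 in female D1 (n = 4) and 11.8 ± 15.9 in female D30 (n = 5). Pmch, a peptide precursor of lateral hypothalamic neurons, had a median of 8.42 CPM. It was 2915 and 1472 CPM in male D30 replicates 7 and 6, 1571 CPM in male saline replicate 7, 2136 and 1422 CPM in female saline replicates 3 and 4, and at most 133 CPM in the others. Hcrt, the orexin precursor of the same hypothalamic area, was 482 and 798 CPM in female saline replicates 3 and 4, 244 and 239 CPM in male D30 replicates 6 and 7, 141 CPM in male saline replicate 7 and at most 21.3 CPM in the others. Female saline thus averaged 609 CPM of Pmch, against 39.5 CPM at D1 and 14.1 CPM at D30. The first principal component of all tested genes held 10.1% of the variance.

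**Figure D1:**
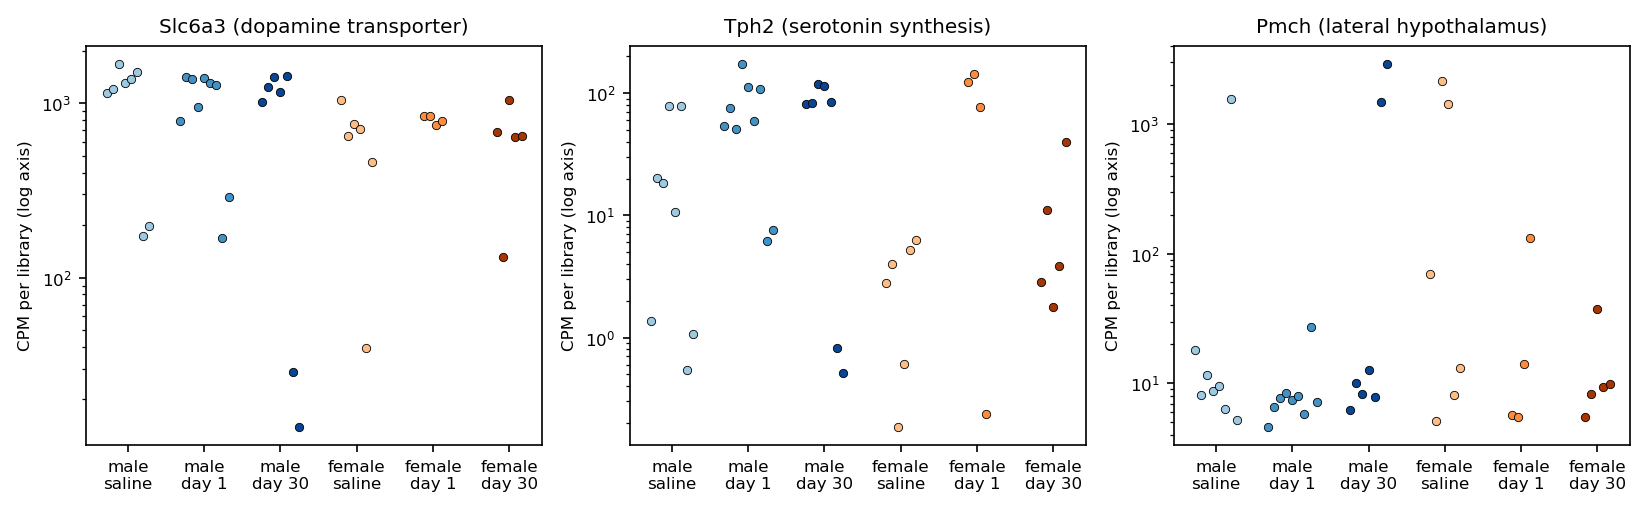
CPM of Slc6a3 (dopamine neurons), Tph2 (raphe serotonin neurons) and Pmch (lateral hypothalamic neurons) on a log axis, 1 point per library in the 6 groups. Slc6a3 spans 13.9 to 1685 CPM and falls under 0.25 of its median in 7 libraries, and Pmch reaches 2915 CPM in 1 male D30 library.

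At 1 day of morphine abstinence, males had higher expression of Sult1a1, a cytosolic sulfotransferase, and of Dcst1, a DC-STAMP domain protein. Sult1a1 rose from 17.8 ± 4.43 CPM in saline (SD, n = 8) to 49.2 ± 26.4 CPM at D1 (n = 9), a log2 fold change of 1.47 (SE 0.26). Dcst1 rose from 2.05 ± 0.47 to 5.29 ± 2.89 CPM, a log2 fold change of 1.36 (SE 0.25). For each, 8 of 9 D1 libraries lay above the saline median and 7 above every saline library (edgeR adjusted p = 0.045 for both). The next genes by p did not pass. They were Pnpla2, the adipose triglyceride lipase, at 0.87 (SE 0.18, adjusted p = 0.175, 8 of 9 libraries above the saline median), the peroxisomal membrane gene Pex11a at 0.96 (SE 0.21) and the collagen cross-linking enzyme Lox at 2.12 (SE 0.47), which was 1.03 (SE 0.30) without male D1 replicate 9.

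Glucocorticoid-responsive genes were higher as a group in D1 males. All 22 measured members had a positive log2 fold change (median 0.57), 1 of them (Sult1a1) passed over all genes, and 14 passed adjusted over the list alone. Examples are the metallothionein Mt2A at 1.29 (SE 0.38), Pdk4, an inhibitor of pyruvate dehydrogenase, at 1.26 (SE 0.34), and Hif3a at 1.24 (SE 0.38). None of these passed over all genes, nor did Sgk1, a serum- and glucocorticoid-induced kinase, at 1.47 (SE 0.37). Fkbp5, a co-chaperone that limits glucocorticoid receptor activity, was 14.8 ± 3.58 CPM in saline and 23.6 ± 8.85 CPM at D1, at 0.67 (SE 0.18, adjusted p = 0.358), above the saline median in 9 of 9 libraries. The list passed in camera (adjusted p = 2.21e-26, and adjusted p = 0.020 with an estimated correlation) and in fry (adjusted p = 0.0335). The list score was higher by 0.62 (SE 0.18), above the saline median in 7 of 9 libraries, and did not pass the exact permutation test after adjustment (adjusted p = 0.209). With an estimated correlation the list no longer passed without the 7 libraries low in Slc6a3 (adjusted p = 0.138, with a score difference of 0.61, SE 0.19, from fewer libraries) or with regional marker components as covariates (adjusted p = 0.269, with a score difference of 0.57, SE 0.23, where the components widened the spread).

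Mural and fibroblast markers were high in 1 D1 male, and 20 of 21 members were positive in the comparison (median 1.13) and 12 past the threshold adjusted over the list alone, all 12 higher. The smooth muscle genes Cnn1 at 3.81 (SE 0.90) and Acta2 at 2.47 (SE 0.62) and the collagen gene Col1a2 at 2.42 (SE 0.67) led the list without passing over all genes. The camera call (adjusted p = 3.13e-06) was lost at adjusted p = 0.857 with an estimated correlation. Male D1 replicate 9 had a list score of 6.50 against 3.08 to 4.19 in the other 8 D1 libraries, and without it the score difference went from 0.47 (SE 0.37) to 0.14 (SE 0.15) and the camera call was lost (adjusted p = 0.173). Without it Cnn1 was at 1.03 (SE 0.54), Acta2 at 0.60 (SE 0.33) and Col1a2 at 0.15 (SE 0.33). Lower genes that did not pass were RT1-CE16, a class I histocompatibility gene, at -3.79 (SE 0.87), Lix1 at -0.48 (SE 0.11), Ndrg3-ps1 at -2.77 (SE 0.70), Asrgl1 at -0.26 (SE 0.07) and the cytokine gene Il21 at -0.86 (SE 0.23). The dopamine genes Th at -0.04 (SE 0.56) and Slc6a3 at -0.11 (SE 0.60) did not pass. Neither did the mu opioid receptor Oprm1 at 0.56 (SE 0.44), the kappa receptor Oprk1 at 0.03 (SE 0.27), or the opioid peptide genes Penk at 0.29 (SE 0.26) and Pdyn at 0.06 (SE 0.45). Bdnf at -0.14 (SE 0.21), the immediate early gene Fos at 0.43 (SE 0.27) and the astrocyte gene Gfap at -0.19 (SE 0.50) did not pass either. In all, 2 of 22493 genes passed, both higher, with 1079 genes at an unadjusted p under 0.05 where chance gives 1125, and DESeq2 called 110. The count was 4 without male D1 replicate 2 or 8, 3 without male D1 replicate 4, 1 without male saline replicate 3 and 0 without any other single library. No low-value filter and the library series as a block each gave 0. So did limma on log2(value + 1), which was not scaled for depth, and the same holds for its counts below.

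At 30 days edgeR called no gene between morphine and saline males, and DESeq2 called 72. The higher genes that led by p were neuropeptide and amine genes of the hypothalamus, Npvf at 8.16 (SE 1.98), Hdc, which makes histamine, at 4.50 (SE 1.15) and Trh, the thyrotropin-releasing hormone precursor, at 3.36 (SE 0.89). Hdc lay above every saline library in 2 of the 7 D30 libraries, male D30 replicate 7 at 60.5 CPM and replicate 6 at 5.70 CPM, both among the libraries low in Slc6a3. Jhy at 1.64 (SE 0.46) and Hnrnph3 at 0.21 (SE 0.06) were next, and RT1-CE16 at -4.12 (SE 0.98), the cytokine Il1b at -1.66 (SE 0.48), Smim13l at -0.46 (SE 0.13), Entpd5 at -0.41 (SE 0.12) and Shisa3 at -1.14 (SE 0.34) were the lowest by p. All of these had an adjusted p of 1.

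Among the fixed genes at D30 in males, Fos was at 0.89 (SE 0.29), Pdyn at 1.13 (SE 0.47), Penk at 0.69 (SE 0.27), Oprm1 at 0.72 (SE 0.46) and Oprk1 at -0.09 (SE 0.29). Bdnf was at 0.06 (SE 0.22), Fkbp5 at -0.14 (SE 0.19), Gfap at -0.07 (SE 0.54), Th at -0.10 (SE 0.60) and Slc6a3 at -0.26 (SE 0.64). All 23 cholesterol synthesis genes had a negative log2 fold change (median -0.22), 0 of them passed over all genes or adjusted over the list alone. The list passed in camera (adjusted p = 3.48e-16), a call lost at adjusted p = 0.388 with an estimated correlation. Immediate early genes were positive in 29 of 33 (median 0.19), with a camera adjusted p of 2.58e-05 and an adjusted p = 0.699 with an estimated correlation, and the preset call was lost with the library series as a block (0.0505) and without the 7 libraries low in Slc6a3 (0.0673). Oligodendrocyte and myelin genes were negative in 23 of 23 (median -0.21), with an adjusted p = 0.887 with an estimated correlation. Male D30 replicate 7 held part of these list differences. Without it the score differences went from -0.23 to -0.15 for cholesterol synthesis, from 0.23 to 0.14 for immediate early genes and from -0.25 to -0.10 for oligodendrocyte and myelin genes. edgeR called 0 of 22493 genes, with 737 at an unadjusted p under 0.05, and limma on log2(value + 1) called 0.

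Between D30 and D1 males, the 2 genes that had passed at D1, Sult1a1 and Dcst1, were lower at D30. Sult1a1 fell from 49.2 ± 26.4 to 17.6 ± 3.99 CPM (n = 9 and 7), a log2 fold change of -1.48 (SE 0.27), and Dcst1 from 5.29 ± 2.89 to 1.89 ± 0.551 CPM, at -1.48 (SE 0.26). Mfsd2a, the lysolipid transporter of brain endothelium, fell from 54.2 ± 14.5 to 30.4 ± 3.89 CPM, at -0.83 (SE 0.14). Pnpla2 at -1.04 (SE 0.19) and Hr, a nuclear receptor corepressor, at -0.70 (SE 0.13) fell as well, and for these 5 genes 7 of 7 D30 libraries lay below the D1 median (edgeR adjusted p = 0.0155). The other lower genes that passed were Wfdc1, Degs2, Hip1, the thiamine transporter Slc19a3, Slc24a4, Pla1a, fibronectin (Fn1, -1.45, SE 0.30, and -1.21, SE 0.27, with an adjusted p of 0.0809 without male D1 replicate 9), Pex11a, Nostrin and the glycerol-3-phosphate dehydrogenase Gpd1 (-1.52, SE 0.32), with adjusted p between 0.0155 and 0.0499. Nim1k, a kinase, was higher at D30 by 0.51 (SE 0.11, adjusted p = 0.0403), above every D1 library in 7 of 7. Hdc passed at 6.10 (SE 1.21, adjusted p = 0.030), was above the D1 median in 3 of 7 libraries and at -0.34 without the 7 libraries low in Slc6a3. Npvf, at 8.47 (SE 1.90, adjusted p = 0.0904), did not pass.

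Glucocorticoid-responsive genes were lower at D30 than at D1 in males, negative in 22 of 22 (median -0.71), with 1 lower over all genes and 14 adjusted over the list alone. The camera call (adjusted p = 2.61e-18) was lost at adjusted p = 0.112 with an estimated correlation, and fry passed (adjusted p = 0.0361). In library series 2 the list score was 3.42 in D1 replicate 4 and 3.29 to 3.93 in the D30 males. In series 1 it was 3.52 to 4.63 in D1 males and 3.84 in D30 replicate 1. Endothelial markers were negative in 17 of 19 (median -0.41, 11 lower adjusted over the list alone, adjusted p = 0.544 with an estimated correlation). Mural and fibroblast markers were negative in 21 of 21 (median -1.33, 16 lower adjusted over the list alone, adjusted p = 0.544 with an estimated correlation). Without male D1 replicate 9 the score differences went from -0.50 (SE 0.36) to -0.16 (SE 0.14) for the mural list and from -0.34 (SE 0.15) to -0.22 (SE 0.09) for the endothelial list. In all, 17 genes passed, 2 higher and 15 lower, with 1872 at an unadjusted p under 0.05. The count was 41 without male D1 replicate 4, 28 without male D1 replicate 2, 19 without male D30 replicate 1, 13 without male D1 replicate 8, 0 without male D30 replicate 7 and 5 to 8 without any other single library. It was 181 with DESeq2, 48 with regional marker components as covariates, and 0 with limma on log2(value + 1), with the library series as a block and without the 7 libraries low in Slc6a3.

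**Figure D2:**
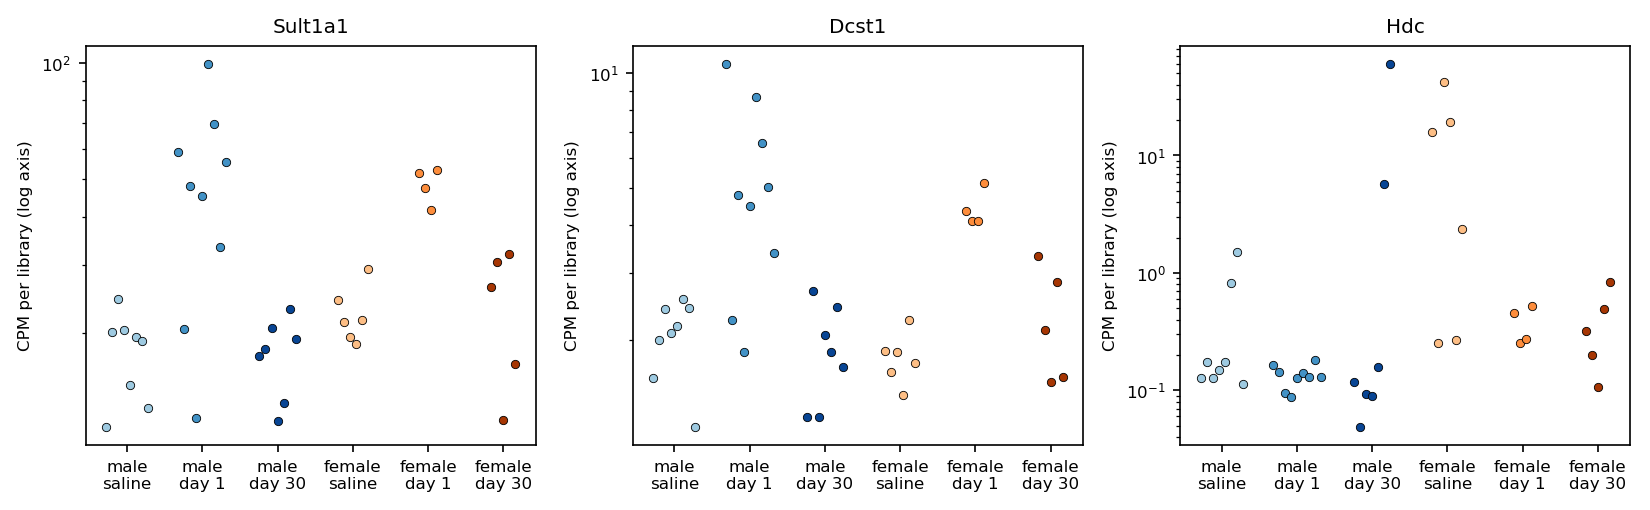
CPM of Sult1a1, Dcst1 and Hdc on a log axis, 1 point per library in the 6 groups. Sult1a1 averages 49.2 CPM in male D1 and 48.4 CPM in female D1 against 17.8 and 22.5 CPM in saline, and Hdc reaches 60.5 CPM in 1 male D30 library.

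In females at 1 day no gene passed in edgeR. Sult1a1 averaged 22.5 ± 3.84 CPM in saline (SD, n = 6) and 48.4 ± 5.08 CPM at D1 (n = 4), a log2 fold change of 1.11 (SE 0.33, adjusted p = 0.706). Fkbp5 was at 0.54 (SE 0.23), above the saline median in 4 of 4. Fah, which breaks down tyrosine products, was at 0.62 (SE 0.12, adjusted p = 0.232), Hr at 0.71 (SE 0.16), Neu4, a sialidase of the oligodendrocyte lineage, at 0.54 (SE 0.12), Pilrb2l2 at 1.19 (SE 0.28) and Gstz1 at 0.38 (SE 0.09), each above every saline library in 4 of 4 libraries. The neutrophil gene S100a9 at -3.28 (SE 0.80), Stk26 at -1.14 (SE 0.29), Epha3 at -0.68 (SE 0.18) and Vstm2a at -0.36 (SE 0.10) were below every saline library in 4 of 4, and Tmem170a, at -3.84 (SE 1.02), was not.

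Glucocorticoid-responsive genes were positive in 21 of 22 in D1 females (median 0.56), 0 of them past the threshold over all genes and 5 adjusted over the list alone. Hif3a was at 1.42 (SE 0.49) and the lipid droplet gene Plin4 at 1.16 (SE 0.43). The list passed in camera (adjusted p = 3.79e-12), a call lost at adjusted p = 0.267 with an estimated correlation, and the list score, higher by 0.61 (SE 0.16) and above the saline median in 4 of 4, had an exact permutation adjusted p of 0.152. Regional markers differed in level between the same libraries, with means in saline and at D1 of 3.18 and 86.0 CPM for Tph2, 609 and 39.5 CPM for Pmch and 216 and 8.03 CPM for Hcrt. With 3 regional marker components as covariates the score difference was 0.53 (SE 0.24, 95% interval -0.0799 to 1.14). Oligodendrocyte and myelin genes were positive in 23 of 23 (median 0.40, 0 adjusted over the list alone, adjusted p = 0.372 with an estimated correlation), with a score difference of 0.43 that was 0.27 without female saline replicate 3. Choroid plexus and ependymal markers were negative in 15 of 15 (median -1.69, adjusted p = 0.267 with an estimated correlation). Female saline replicates 6 and 3 stood apart in that list with scores of 3.48 and 2.58, against 0.640 to 1.43 in the other saline females. Of the fixed genes, Pdyn was at -1.73 (SE 0.62), Th at 0.49 (SE 0.74), Slc6a3 at 0.40 (SE 0.79) and Oprm1 at -0.37 (SE 0.58). Oprk1 was at 0.18 (SE 0.36), Penk at 0.05 (SE 0.34), Bdnf at -0.14 (SE 0.28), Fos at -0.20 (SE 0.36) and Gfap at 0.30 (SE 0.67). edgeR called 0 genes, with 1533 at an unadjusted p under 0.05, limma on log2(value + 1) 0 and DESeq2 136. edgeR called 1 gene without female saline replicate 1 and 2 without the 7 libraries low in Slc6a3.

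**Figure D3:**
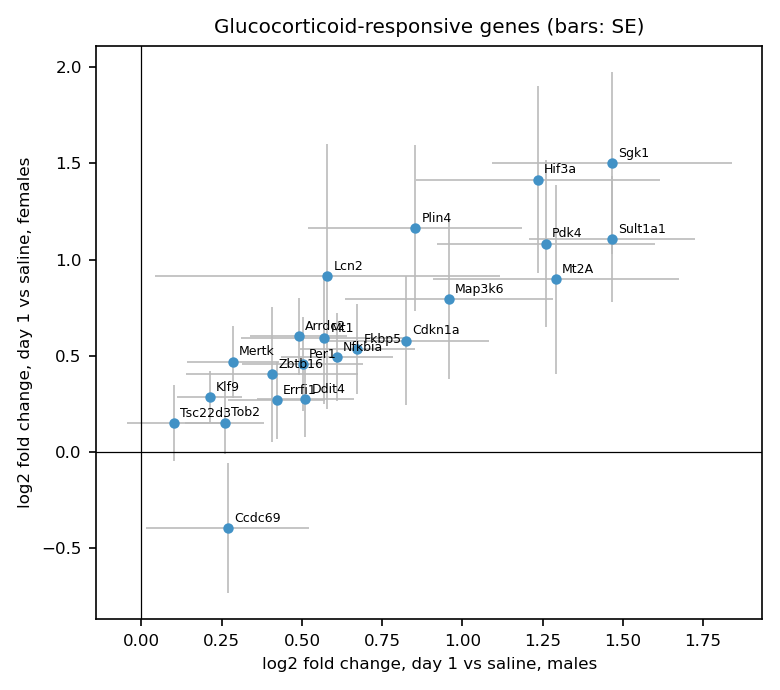
Log2 fold change of D1 against saline for the 22 measured glucocorticoid-responsive genes, males on the x axis and females on the y axis, with bars of 1 SE. All 22 are positive in males and 21 in females, and Hif3a lies at 1.24 and 1.42.

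Females at 30 days had high heat shock gene expression in some libraries. Hspa1a, an inducible HSP70 chaperone, was 9.21 ± 2.18 CPM in saline (SD, n = 6) and 55.4 ± 93.7 CPM at D30 (n = 5), a log2 fold change of 2.59 (SE 0.52, adjusted p = 0.276, above every saline library in 3 of 5). Female D30 replicate 2, a library low in Slc6a3, held 222 CPM. Its near-identical copy Hspa1b was at 3.33 (SE 0.71). Heat shock and chaperone genes were positive in 23 of 26 (median 0.24), 4 adjusted over the list alone. The camera call (adjusted p = 5.84e-11) was lost at adjusted p = 0.694 with an estimated correlation, and without replicate 2 the score difference went from 0.314 to 0.140. Other genes that led by p and did not pass were Wrn, a DNA helicase, at 0.45 (SE 0.12), Abca8a at 0.46 (SE 0.13), Lca5l at -2.36 (SE 0.54), Lrrn4cl at -3.81 (SE 0.87) and Tmem170a at -3.94 (SE 0.93). The Y-linked Kdm5d averaged 0.122 CPM at D30 and 0.0221 CPM in saline, with 0.429 CPM in female D30 replicate 4 and 0.107 CPM in replicate 3. These 2 libraries also held traces of Ddx3y (0.759 and 0.375 CPM) and Eif2s3y (1.39 and 0.535 CPM), both 0 in the other 3 D30 libraries. Female saline replicate 1 held traces as well, with 0.312 CPM of Ddx3y and 0.624 CPM of Eif2s3y. The small nucleolar RNA Snora84 was 5.93 ± 3.61 CPM in saline and 0 in all 5 D30 libraries.

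Of the fixed genes at D30 in females, Pdyn was at -1.81 (SE 0.58), Fos at 0.75 (SE 0.33), Fkbp5 at 0.16 (SE 0.22), Th at 0.07 (SE 0.70) and Slc6a3 at 0.05 (SE 0.75). Oprm1 was at 0.05 (SE 0.53), Oprk1 at 0.04 (SE 0.34), Penk at -0.10 (SE 0.32), Bdnf at -0.11 (SE 0.26) and Gfap at -0.46 (SE 0.63). edgeR called 0 genes, with 1381 at an unadjusted p under 0.05, limma on log2(value + 1) 0 and DESeq2 144. edgeR called 1 gene without female D30 replicate 1 or 4.

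Between D30 and D1 females, chaperone genes again led without passing. Hsph1 was at 0.72 (SE 0.13, adjusted p = 0.110) and above every D1 library in 5 of 5, Hspa1a at 3.05 (SE 0.61) in 4 of 5 and Dnajb1, an HSP40 co-chaperone, at 0.74 (SE 0.16) in 4 of 5. Heat shock and chaperone genes were positive in 23 of 26 (median 0.33), with 10 higher adjusted over the list alone and 0 over all genes. The list passed in camera (adjusted p = 5.02e-19), a call lost at adjusted p = 0.103 with an estimated correlation, and without female D30 replicate 2 the score difference went from 0.409 to 0.235. Lmntd2 at -2.67 (SE 0.54), the sulfatase Arsg at -0.41 (SE 0.08) and Thnsl2 at -0.56 (SE 0.13) were below every D1 library in 5 of 5. Glucocorticoid-responsive genes were negative in 19 of 22 (median -0.26, adjusted p = 0.986 with an estimated correlation, and 0.0832 at the preset one with regional marker components as covariates). edgeR called 0 genes, with 1204 at an unadjusted p under 0.05, limma on log2(value + 1) 0 and DESeq2 140. edgeR called 11 genes without female D30 replicate 1 and 1 without female D30 replicate 4.

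**Figure D4:**
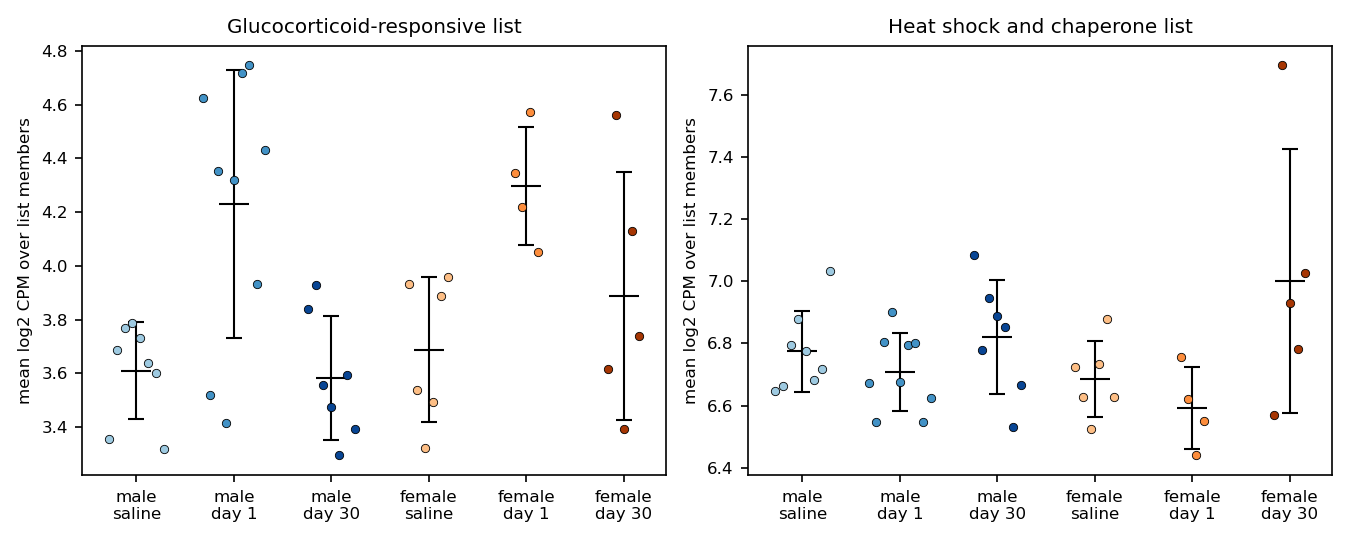
Score of the glucocorticoid-responsive and the heat shock and chaperone lists (mean log2 CPM of the members), 1 point per library in the 6 groups, with bars of mean ± SD. The glucocorticoid score averages 4.23 in male D1 and 4.30 in female D1 against 3.61 and 3.69 in saline, and the heat shock score of female D30 replicate 2 is 7.69.

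In saline 137 genes differed between the sexes, 11 on the X chromosome, 7 on the Y chromosome and 119 elsewhere, and 8 of the 137 were cholesterol synthesis genes. Xist averaged 86.6 ± 18.1 CPM in females (n = 6) and 0.0257 CPM in males (n = 8). The Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty averaged 44.9, 14.1, 80.7 and 5.27 CPM in males and each averaged at most 0.125 CPM in females. The X-linked histone demethylases Kdm6a at 0.65 (SE 0.10) and Kdm5c at 0.59 (SE 0.09), Jpx at 0.60 (SE 0.15) and Eif2s3 at 0.36 (SE 0.09) were higher in females in 6 of 6 libraries. Ddx3x at 0.23 (SE 0.09), Ftx at 0.21 (SE 0.21) and Usp9x at 0.04 (SE 0.07) did not pass. Zfp444 rose by 0.35 (SE 0.06, adjusted p = 0.00121, 6 of 6). Tmem170a passed at 4.96 (SE 0.81), above every male library in 4 of 6. Of 23 cholesterol synthesis genes, 22 were lower in females (median -0.45), 8 passed over all genes and 18 adjusted over the list alone. The 8 were Hmgcs1 (-0.66, SE 0.13), Msmo1 (-0.62, SE 0.12), Nsdhl (-0.50, SE 0.09, adjusted p = 0.0023, below every male library in 6 of 6), Sqle, Idi1, Cyp51, Fdps and Fdft1. The camera call (adjusted p = 4.67e-16) was lost at adjusted p = 0.219 with an estimated correlation, fry passed (adjusted p = 0.00471), and the list score, lower by 0.41 (SE 0.09) in 6 of 6, passed the exact permutation test (adjusted p = 0.0266). In this comparison 8 of 32 lists passed the exact test, so the pass was not particular to cholesterol synthesis. Within library series 4, with 4 female and 3 male saline libraries, the score differed by -0.24.

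X-linked escape genes, which stay active on the inactive X chromosome, were positive in 8 of 8 in saline (5 past the threshold over all genes, adjusted p = 9.3e-07 with an estimated correlation). The list includes Xist, so its calls between the sexes, here and at D1 and D30, largely follow from the sex of the animals. Cytosolic ribosomal protein genes were lower in saline females in 78 of 79 (median -0.24, 2 over all genes and 42 adjusted over the list alone, adjusted p = 0.345 with an estimated correlation, exact permutation adjusted p = 0.028 for the score). Oligodendrocyte and myelin genes were lower in 22 of 23 (median -0.44, 13 adjusted over the list alone, adjusted p = 0.345 with an estimated correlation). Regional markers differed in level between the same groups. Means in saline males and females were 1940 and 1040 CPM for Th, 1075 and 610 for Slc6a3, 205 and 609 for Pmch and 18.3 and 216 for Hcrt. Of the 137 genes, 75 were higher and 62 lower in females, and 4743 genes had an unadjusted p under 0.05. The count was 323 without male saline replicate 7, 288 without female saline replicate 5, 166, 138 and 110 without female saline replicates 2, 4 and 6, 96 without male saline replicate 6 and 49 to 84 without any other single library. It was 762 with DESeq2, 11 with limma on log2(value + 1), 44 with the library series as a block and 2595 without the 7 libraries low in Slc6a3.

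At D1 the sexes differed in 10 genes, 4 higher and 6 lower in females, with 3 on the X and 5 on the Y chromosome (2109 at an unadjusted p under 0.05). Xist averaged 97.1 ± 7.18 CPM in females (n = 4) and 0.0451 CPM in males (n = 9). Kdm6a at 0.63 (SE 0.11) and the RNA methylation factor Zc3h13 at 0.33 (SE 0.05, adjusted p = 0.00147) were above every male library in 4 of 4. Ddx3y, Kdm5d, Eif2s3y and Uty were lower, each averaging at most 0.0887 CPM in females. Kdm5c at 0.48 (SE 0.10), Eif2s3 at 0.44 (SE 0.09), Jpx at 0.72 (SE 0.16), Ddx3x at 0.26 (SE 0.09), Ftx at 0.34 (SE 0.23) and Usp9x at -0.06 (SE 0.08) did not pass. X-linked escape genes were positive in 7 of 8 (2 over all genes, Xist and Kdm6a, adjusted p = 2.46e-08 with an estimated correlation). Of the cholesterol synthesis genes, 22 of 23 were lower in females (median -0.33, 10 adjusted over the list alone, 0 over all genes, adjusted p = 0.355 with an estimated correlation). The count was 154 with DESeq2, 72 without the 7 libraries low in Slc6a3, and 9 to 13 without any single library.

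At D30 the sexes differed in 244 genes, 122 higher and 122 lower in females, with 22 on the X chromosome, 7 on the Y chromosome and 215 elsewhere (3737 at an unadjusted p under 0.05). Xist averaged 93.1 ± 8.06 CPM in females (n = 5) and 0.0632 CPM in males (n = 7). Kdm6a at 0.74 (SE 0.11), Kdm5c at 0.60 (SE 0.10), Jpx at 0.62 (SE 0.16), Eif2s3 at 0.52 (SE 0.09) and Ddx3x at 0.40 (SE 0.09) were higher in 5 of 5. Smim10l1 at 0.57 (SE 0.08, adjusted p = 2.91e-05) and Smim13l at 0.97 (SE 0.15) rose in 5 of 5, and Med26, a Mediator subunit, was at -1.5 (SE 0.24, adjusted p = 0.00046, 5 of 5). Ddx3y, Kdm5d, Eif2s3y and Uty were lower, each averaging at most 0.384 CPM in females, and Ftx at -0.03 (SE 0.23) and Usp9x at 0.08 (SE 0.08) did not pass. X-linked escape genes were positive in 7 of 8 (6 over all genes, adjusted p = 1.18e-07 with an estimated correlation). Of the cholesterol synthesis genes, 20 of 23 were lower in females (median -0.26, Nsdhl past the threshold over all genes, 7 adjusted over the list alone, adjusted p = 0.766 with an estimated correlation). The count was 548, 517 and 506 without female D30 replicate 4, male D30 replicate 7 and male D30 replicate 6, 248 without male D30 replicate 1 and 54 to 130 without any other single library. It was 864 with DESeq2, 20 with limma on log2(value + 1), 81 with the library series as a block, 2833 with regional marker components as covariates and 1620 without the 7 libraries low in Slc6a3. Of the genes called, 9 passed in all 3 comparisons between the sexes, and 47 passed in saline and at D30 in the same direction where independent lists would share 0.743. Part of this overlap follows from the sex of the animals, as the calls held 7 Y-linked genes in saline and 7 at D30. The 0.743 also takes genes as independent, which they are not, so the excess does not measure how far other sex differences repeated.

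No gene passed in edgeR in the test of whether the morphine effect differed between the sexes. For D1, the leading estimates for females minus males were Bc1, a neuronal non-coding RNA, at 1.90 (SE 0.47), Lto1 at 1.63 (SE 0.39), Prdm6 at -4.32 (SE 1.26), Hgd at -3.40 (SE 1.00) and Gypc at -2.40 (SE 0.72), all with an adjusted p of 1. Snora35 had a mean of 2.28 CPM in D1 females and was 0 in all male D1 and female saline libraries. For D30 they were Wrn at 0.69 (SE 0.16, adjusted p = 0.278) and the hypothalamic genes Trh at -8.05 (SE 1.5, adjusted p = 0.116), Hdc at -9.55 (SE 1.91) and Npvf. Hdc was 15.8, 42.5 and 19.2 CPM in female saline replicates 1, 3 and 4 and at most 0.832 CPM in female D30, and 5.70 and 60.5 CPM in male D30 replicates 6 and 7. The other leading genes, Kdm5d (among females highest in D30 replicates 4 and 3, and 14.1 CPM or more on average in each male group) and Mir344b-2, averaged 0.122 and 0.578 CPM in D30 females. The glucocorticoid-responsive list did not pass for D1 and had a camera adjusted p of 0.0167 for D30 (19 of 22 positive, adjusted p = 0.801 with an estimated correlation), and its direction turned with the library series as a block (adjusted p = 0.532). The female D30 score difference from saline in that list was 0.20 (SE 0.23), and 0.03 (SE 0.19) without female D30 replicate 2. edgeR called 0 genes for D1, with 852 at an unadjusted p under 0.05, and 0 for D30, with 1419; limma on log2(value + 1) called 0 in each, and DESeq2 64 and 98. edgeR called 1 gene for D30 without female saline replicate 5.

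Across the 22493 genes, which are not independent replicates, log2 fold changes against saline had a Pearson correlation between males and females of 0.0853 at D1 (permutation p = 0.168, 100 permutations of the condition labels) and -0.0728 at D30 (permutation p = 0.287). Within a sex, the D1 and D30 effects share their saline libraries. Their correlation was 0.433 in males, where 100 permutations of the condition labels within the sex gave a mean of 0.494. In females it was 0.464, where the permutations gave 0.420. The covariance was 0.0563 against a mean of 0.0716 with permuted labels in males, and 0.109 against 0.0967 in females. With the saline libraries split between the effects, the correlation averaged -0.082 over 70 splits in males and -0.00442 over 20 splits in females.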

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

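The explanations below were tested on the same samples after the results were seen, and which lists received a count over splits was also chosen after the splits were seen. The predictions for the vascular and glial covariates and for the clock genes (glucocorticoid-responsive list) and for the oligodendrocyte covariates (cholesterol synthesis list) were written before those tests were run. Each comparison was repeated on 100 splits of the same samples, the real one included. At least 2 genes were called by 1 split for D1 against saline in males (highest other count 1), at least 17 by 4 splits for D30 against D1 in males (3781), at least 137 by 1 split for females against males in saline (8), at least 10 by 28 splits at D1 (377) and at least 244 by 3 splits at D30 (2205). A split that called several times the real number may point to structure of the samples other than the groups, and what that structure was remains open. For the comparisons with 0 calls, 100 of 100 splits called as many, with highest other counts of 651 (D30 against saline, males), 27 (D1 against saline, females), 13 (D30 against saline, females), 13 (D30 against D1, females), 8 (sex by D1) and 232 (sex by D30).

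As many lists as the real 7 were called by 77 splits for D1 against saline in males (highest other 16), 8 by 64 for D30 against saline (18) and 9 by 77 for D30 against D1 (23). In females these were 16 lists by 2 splits for D1 against saline (17), 8 by 67 for D30 against saline (14) and 12 by 25 for D30 against D1 (16). Between the sexes they were 16 by 8 in saline (20), 9 by 66 at D1 (16) and 10 by 51 at D30 (21), and for the interactions 16 by 3 for D1 (16) and 7 by 82 for D30 (20). A preset-correlation camera call alone could thus arise from how these samples differ, as with the 77 splits of D1 against saline in males.

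The glucocorticoid-responsive list, weighed first, had a D1 coefficient over both sexes of 0.615 (SE 0.131, 27 libraries, permutation p = 0.00014). In males 1 of 100 splits gave a camera p as small as the real 6.91e-28 (smallest p of the other splits 7.93e-22). It was 1 as small as 2.92e-13 in females (smallest other 7.8e-12) and 4 as small as 8.16e-20 for D30 against D1 in males (smallest other 5.93e-36). With the endothelial, mural and fibroblast, oligodendrocyte and oligodendrocyte precursor list scores as covariates the coefficient was 0.525, which argued against these 4 as the whole cause. Astrocyte and microglia scores were not among the covariates, so their part was not tested. With the library series as a term it was 0.624. Within series the difference was 0.81, -0.27, 0.83 and 0.66 in males (3, 1, 3 and 2 D1 against 1, 1, 3 and 3 saline libraries). In females the Blue series alone held both groups, at 0.35 with 2 D1 libraries and 1 saline library. This argued against the series as the whole cause in males and could not decide it in females. With 3 regional marker components, which share no gene with the list, the D1 coefficient was 0.535 (95% interval 0.228 to 0.842). It was 0.57 in males (0.0574 to 1.08) and 0.53 in females (-0.0799 to 1.14). These values argued against dissection as the whole cause over both sexes but not in females alone. An index of opposed clock genes was lower at D1 by -0.192 (permutation p = 0.00183), -0.239 in males (permutation p = 0.00585) and -0.110 in females (95% interval -0.288 to 0.0675, permutation p = 0.191), so a difference in time of day of collection could not be told apart from an effect of morphine or its withdrawal. The morphine groups are the biological explanation that the design offers, and it may act together with time of day.

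The cholesterol synthesis list, lower in females, was weighed second. Its sex coefficient was -0.317 over 39 libraries (permutation p = 4e-05). With oligodendrocyte scores as covariates it was -0.217, with 3 regional marker components -0.245 (permutation p = 1e-05, the smallest the permutations allow) and with the library series -0.323, and these argued against each as the whole cause. Within series the difference in saline was -0.39 (1 female against 1 male library) and -0.24 (4 against 3). It was -0.61 at D1 (2 against 1) and -0.37 at D30 (1 against 4), so only -0.24 rests on several libraries of each sex. A camera p as small as the real one came from 2 splits in saline (4.38e-17, smallest other p 9.98e-19), 1 at D1 (7.46e-13, smallest other 6.95e-12) and 18 at D30 (2.46e-06, smallest other 9.11e-14). A sex difference may therefore hold in saline and at D1, and at D30 it could be chance with 18 of 100 splits as small. Male D30 replicates 6 and 7, low in Slc6a3, scored 6.18 and 5.92. The other male D30 libraries scored 6.44 to 6.67 and female D30 libraries 6.13 to 6.24. Other males low in Slc6a3 went both ways, with 6.21 in saline replicate 7, 6.29 in D1 replicate 8 and 6.66 in saline replicate 8. Whether chance or dissection weakened the D30 result could thus not be told apart.

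The heat shock and chaperone list, higher in female D30, was weighed last. Without female D30 replicate 2 the score difference went from 0.314 (95% interval -0.0936 to 0.722) to 0.140 (-0.0909 to 0.371) against saline and from 0.409 (-0.119 to 0.937) to 0.235 (-0.0569 to 0.527) against D1, so 1 library may carry much of the first, and the second could not be told apart from it. Replicates 3 and 5, at 6.93 and 7.03, also lay above every saline library (highest 6.88). Within groups and without that library, libraries low in Slc6a3 differed from the others by -0.0447 (95% interval -0.184 to 0.0952), under 0.5 of the 0.869 by which replicate 2 exceeded the other D30 females, which argued against dissection as the whole cause. Within groups, a higher heat shock score went with lower Rbm3 and Cirbp, genes induced by mild cold (-0.403 for the weaker, last part of the text). That test removed group means and left out replicate 2, so it cannot tell whether warmth raised the D30 females or replicate 2.

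For this list a camera p as small as the real one came from 5 splits against saline (real 1.83e-12, smallest other 6.11e-15). Against D1 it came from 5 as well (real 1.57e-20, smallest other 2.34e-27). Other lists gave 4 splits for cholesterol synthesis in D30 males (1.09e-17; 1.1e-19), 4 for ribosomal protein genes between the sexes in saline (6.86e-25; 2.43e-42) and 12 for oligodendrocyte and myelin genes in D1 females (4.43e-14; 1.87e-25).

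Of 84 groups of values examined, 9 held a sample far from the others, where chance gives 4.2. Th was 67.4 CPM in female saline replicate 5 (others 730 to 1605) and 183 CPM in female D30 replicate 2 (1101 to 1653). Slc6a3 was 39.6 CPM (457 to 1043) and 131 CPM (641 to 1046) in the same libraries. Tph2 was 0.237 CPM in female D1 replicate 4 (76.9 to 143). Pmch was 1571 CPM in male saline replicate 7 (5.18 to 18.1) and 27.3 CPM in male D1 replicate 8 (4.63 to 8.42). The total was 63.1 M in male D1 replicate 2 (15.2 M to 35.2 M), and the cholesterol synthesis score 6.21 in male saline replicate 7 (6.59 to 6.88).

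For the sex by D1 test 16 lists passed in camera, with the adjusted p at an estimated correlation in brackets. They were ribosomal protein genes at 1.64e-13 (0.519), oligodendrocyte and myelin genes at 5.43e-10 (0.377), microglia markers at 4.35e-06 (0.377), oligodendrocyte precursor markers at 1.23e-05 (0.377) and immediate early genes at 1.62e-05 (0.377). Choroid plexus markers were at 6.58e-05 (0.377), dopamine neuron genes at 0.000211 (0.604), voltage-gated potassium channels at 0.00164 (0.377), astrocyte markers at 0.0073 (0.519) and oxidative phosphorylation genes at 0.0073 (0.914). Signalling genes of cAMP and CREB were at 0.0101 (0.377), mural and fibroblast markers at 0.0127 (0.620), cholesterol synthesis at 0.0162 (0.650), neurotrophin and neuropeptide genes at 0.0432 (0.561), GABA receptors at 0.0432 (0.519) and red blood cell genes at 0.0486 (0.604). Of these, red blood cell genes turned direction without the Blue libraries (0.758) and oxidative phosphorylation genes without male saline replicate 8 (0.485). For D30 there were 7 lists, oligodendrocyte and myelin genes at 9.28e-12 (0.801), heat shock genes at 0.000323 (0.801), cholesterol synthesis at 0.000661 (0.801), oxidative phosphorylation at 0.000874 (0.810), oligodendrocyte precursor markers at 0.00388 (0.801), dopamine neuron genes at 0.00394 (0.801) and glucocorticoid-responsive genes at 0.0167 (0.801). With the library series as a block, heat shock (0.729), dopamine neuron (0.599) and glucocorticoid-responsive genes (0.532) turned direction. Oxidative phosphorylation genes turned with regional marker components (0.0119), and they and heat shock genes turned without the 7 libraries low in Slc6a3 (0.595 for both).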

How the results depend on the processing

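Across the settings, genes named in the text kept their direction and their side of the threshold in 2437 cases, passed newly in 63, no longer passed in 143 and turned direction in 1. List calls kept their direction and still passed in 467 cases, no longer passed in 556 and turned direction in 39. Depth limits genes of low level. The cause of the changes below was not tested, except that fewer libraries were used where some were left out. Regional marker components, the libraries low in Slc6a3, robust edgeR, voom weights and the protein-coding settings were chosen after seeing the data.

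Genes called for D1 against saline in males (2) were 0 with limma on log2(value + 1), log2(value + 5) or log2 CPM, no filter, quantile normalization, the library series, no Blue libraries, array weights, voom weights, marker components, no libraries low in Slc6a3 or separate fits, and 110 with DESeq2. DESeq2 called 72 (D30, males), 136 (D1, females), 144 (D30, females), 140 (D30 against D1, females), 64 (sex by D1) and 98 (sex by D30) where edgeR called 0. For D30 against D1 in males (17) the count was 0 with limma on either log2 value, quantile normalization, the series, separate fits or no low libraries, 9 with log2 CPM, 26 with array weights, 10 with voom weights, 48 with marker components and 181 with DESeq2. D1 against saline in females gave 2 without the low libraries, and D30 against D1 in females 1 without Blue libraries, 5 with array weights and 5 with marker components.

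Females against males in saline (137) gave 10 and 11 with limma on log2(value + 5) and log2(value + 1), 83 with log2 CPM, 44 with the series, 81 without Blue libraries, 502 with array weights, 491 with voom weights, 2595 without the low libraries, 88 with separate fits and 762 with DESeq2. At D1 (10) the counts were 19 with quantile normalization, 654 with array weights, 522 with voom weights, 18 with marker components, 72 without the low libraries and 154 with DESeq2. At D30 (244) they were 19 and 20 with limma, 125 with no filter, 437 with quantile normalization, 81 with the series, 3612 with array weights, 3624 with voom weights, 2833 with marker components, 1620 without the low libraries, 41 with separate fits and 864 with DESeq2. The 118 list calls became 4 with an estimated correlation, 8 with fry, and, with an estimated correlation, 4 without the low libraries and 3 with marker components.

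With a replicate block, 0 genes were called for D1 against saline in males, 11 for D30 against D1 in males, 2 for D1 against saline in females, and 1866, 30 and 775 between the sexes in saline, at D1 and at D30. The numbers did not pair the samples: r of 80 same-number pairs averaged 0.0135, 6 were over 0.1, and 12 of 39 libraries correlated best with their own number.

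Leaving out each library in turn gave 0 to 4 genes for D1 against saline in males, 0 to 41 for D30 against D1 in males, 0 to 1 for D1 and for D30 against saline in females, 0 to 11 for D30 against D1 in females, 49 to 323, 9 to 13 and 54 to 548 between the sexes in saline, at D1 and at D30, 0 to 1 for sex by D30, and 106 to 125 list calls.

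Hdc in D30 against D1 males turned to -0.34 without the low libraries. These lists turned direction, with the adjusted p there. Quantile normalization: ribosomal genes between the sexes at D1, 0.196. Library series: dopamine genes in D30 against saline males 0.687, cholesterol synthesis in D30 against D1 males 0.844, microglia in D1 against saline females 0.660 and in D30 against D1 females 0.273, ribosomal genes in the latter 0.990, and for sex by D30 dopamine 0.599, glucocorticoid-responsive 0.532 and heat shock genes 0.729. No Blue libraries: in D1 against saline females astrocyte 0.881 and red blood cell genes 0.647, in D30 against D1 females astrocyte 0.626 and oxidative phosphorylation genes 0.0765, ribosomal genes between the sexes at D1 0.909, and red blood cell genes for sex by D1 0.758. Marker components (in brackets with an estimated correlation): oxidative phosphorylation in D30 against saline males 0.000369 (0.637) and females 0.528 (0.944), in D30 against D1 females 0.00261 (0.953) and for sex by D30 0.0119 (0.772), and dopamine genes in D1 against saline females 0.00638 (0.244), between the sexes in saline 0.0104 (0.223) and for sex by D1 0.481 (0.744). No low libraries (likewise): oxidative phosphorylation in D1 against saline males 0.0341 (0.826), in D30 against saline males 5.12e-15 (0.574) and for sex by D30 0.595 (0.906), cholesterol synthesis in D30 against D1 males 0.651 (0.891) and heat shock genes for sex by D30 0.595 (0.906). Dopamine genes make up 27 of the genes behind the components, so their turn there shows nothing. Single libraries left out turned 7 list calls in 6 tests. Over all libraries left out in turn, the adjusted p of each ranged as follows, with the turned value in brackets. Oxidative phosphorylation genes: 8.12e-11 to 0.332 in D1 against saline males (0.332 without male saline replicate 8), 1.36e-08 to 0.715 in D30 against saline males (0.00908 without male saline replicate 8, 0.715 without male D30 replicate 7), 1.31e-05 to 0.918 in D30 against D1 females (0.918 without female D1 replicate 3) and 1.1e-06 to 0.900 for sex by D1 (0.485 without male saline replicate 8). Ribosomal genes: 4.86e-07 to 0.820 in D30 against D1 males (0.642 without male D30 replicate 5). Endothelial markers: 0.00128 to 0.965 in D30 against D1 females (0.965 without female D30 replicate 4).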

Other observations

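Other lists passed in camera at the preset correlation and lost the call with an estimated one. In D1 females against saline, 30 of 37 voltage-gated potassium channel genes, which set neuronal excitability, had a negative log2 fold change (median -0.30, adjusted p = 0.304 with an estimated correlation), as had 13 of 17 GABA receptor genes (median -0.31, adjusted p = 0.496 with an estimated correlation). The GABA receptor list also lost its preset call with the library series as a block (0.108), without the Blue libraries (0.0951) and without female D1 replicate 3 (0.0612). Markers of neighbouring regions went with the same groups, as Pmch averaged 609 CPM in saline and 39.5 CPM at D1, Hcrt 216 and 8.03 CPM, Hdc 13.4 and 0.377 CPM and Tph2 3.18 and 86.0 CPM. Pmch was 2136 and 1422 CPM in female saline replicates 3 and 4. With regional marker components as covariates the potassium channel list had an adjusted p of 0.000404 and the GABA receptor list of 0.000188, and both had 0.244 with an estimated correlation. Microglia markers were positive in 18 of 22 (median 0.22, adjusted p = 0.496 with an estimated correlation), and the score difference of 0.22 was 0.15 without female saline replicate 5. Their direction turned with the library series as a block (adjusted p = 0.660), where D1 and saline females share the Blue series alone, and the call was lost with regional marker components (adjusted p = 0.204). Between the sexes in saline, 86 of 88 nuclear-encoded oxidative phosphorylation genes were lower in females (median -0.30, 10 adjusted over the list alone, adjusted p = 0.373 with an estimated correlation). Male saline replicate 8 stood apart with a score of 8.57, and without it the score difference went from -0.28 (SE 0.13) to -0.17 (SE 0.09). At D1, astrocyte markers were higher in females in 20 of 20 (median 0.26, adjusted p = 0.355 with an estimated correlation), and the score difference of 0.24 was 0.12 without female D1 replicate 3 and the preset call was lost without the Blue libraries (adjusted p = 0.219).

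A hypothesis formed from the data was that a high heat shock score went with warmer tissue or animals. Rbm3 and Cirbp encode RNA-binding proteins induced by mild cold, and the prediction was a negative correlation of both with the score within groups. Over 39 libraries r was -0.745 for Rbm3 (permutation p = 1e-05, the smallest the permutations allow) and -0.548 for Cirbp (permutation p = 4e-04). Without female D30 replicate 2 they were -0.692 and -0.403, and without the 2 farthest libraries -0.649 and -0.305 (permutation p = 0.07 for the last). Within library series 1 to 4, r was -0.886, -0.806, -0.726 and -0.559 for Rbm3 and -0.817, -0.493, -0.611 and -0.382 for Cirbp. The prediction was met, with -0.403 as the weaker of the 2 values, but it and its cut were written after the results were seen, so this is no independent support. The correlations describe the spread within groups and not differences between groups. Temperature itself was not measured, so warmth may be 1 of several causes of that spread.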
